A study of Arabidopsis thaliana with 2 samples.

How the data were processed

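Bisulfite treatment turns unmethylated cytosine into uracil, which is read as T, so the share of reads that still show C at a cytosine is its methylation level. The series holds whole-genome bisulfite sequencing of 14-day-old Arabidopsis thaliana seedlings of 2 mutants, arp6-5 and pie1-7, with 1 library each. A wild type and further libraries of either mutant were not analysed here.

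The submitters' processing notes name Trimmomatic, BSMAP and the TAIR10 build; versions and settings are not given in the sources used here. Each of the 10 files lists the cytosines of 1 chromosome of 1 library. Per the file headers, the authors gave for each cytosine its position, strand and context, the count of reads showing C, the count of reads showing C or T, the counts of G and of G or A on the opposite strand, an effective count and a ratio. The effective count is an estimated count: at every deposited cytosine it equalled the C or T count times the G share of the opposite strand, within a tolerance of 0.0051, so that a C-to-T variant lowers it. The ratio in the deposited files is a fraction and equalled the C count over the effective count, at most 1, within the same tolerance. No listed cytosine had fewer than 4 reads in its library. CG is a cytosine before guanine; in CHG and CHH, H stands for A, C or T.

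Cytosines listed in both libraries were used. The methylation level of a region was the summed C count over the summed effective count, with the C count capped at the effective count. Sums were rounded to whole numbers for tests. Windows of 200 bp with at least 4 cytosines of a context were compared by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the context, and called at an adjusted p under 0.01 and a difference of at least 40 (CG), 20 (CHG) or 10 (CHH) percentage points. Called windows of one direction within 200 bp of each other were merged. Gene bodies and 1 kb flanks with at least 10 cytosines were compared in the same way, with a threshold of 20 points for CG. These tests weigh the reads of 2 libraries against each other and do not compare genotypes, since there is no replicate. Intervals are exact Clopper-Pearson 95% intervals and cover counting error only. Read counts of a region are sums over its cytosines, so a read that covers several cytosines is counted at each. Reads also have no molecular identifiers. Tests and intervals treat the counts as independent, so p-values can be too small and intervals too narrow. Median summed depth per tested CG window was 141 reads in arp6-5 and 131 in pie1-7. As a background inside each library, the plus and minus strands of a library were compared in windows with at least 4 cytosines on each strand.

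Gene positions came from a RefSeq gene table of assembly TAIR10.1, used for names and for which gene a cytosine lies in or beside; no coordinate of that table is given. The fit between table and files was checked on the data: the lowest CG level around gene ends lay within 100 bp of the table's ends in 24 of 25 blocks of 5 Mb, with shifts of up to 3000 bp tried. The table has no strand, exons, untranslated regions or transposon classes. The planned upstream tests were therefore run on both flanks, the lower-coordinate and the higher-coordinate one, and pseudogenes were the repeat-like class used. Pericentromeres were taken as 3 Mb to either side of 15, 3.6, 14, 4 and 12 Mb on chromosomes 1 to 5.

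The main tests, their thresholds, most alternatives and the 9 gene lists were fixed before the data were examined; the same weight per site, the chromosome 2 stretch left out, single strands, the bounds for a library shift and the test of conversion were chosen afterwards. The rule for named genes took, for CG in bodies and CG, CHG and CHH in flanks, the 3 called genes with the largest difference per direction; from each list up to 3 called members, or the member with the largest flank CG difference where none was called; and ARP6, PIE1, FLC and ROS1. Named regions were the 3 with the most called windows per direction in CG and CHH, with ties, for which no rule had been fixed, going to the larger difference. A list's median was placed among 10000 random lists of the same size matched on methylation level. On simulated reads over the real windows, with 200 windows changed, the test recovered 200 CG windows shifted by 60 points, 180 CHG windows shifted by 30 and 196 CHH windows shifted by 15, with at most 1 false call in each. The simulated counts were drawn independently, with no variation between molecules, strands or libraries beyond sampling. The simulation therefore checks the code and gives no rate of false calls for the real libraries.

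Alternatives varied the read minimum, the weighting of sites, window and flank lengths, thresholds, depth (arp6-5 thinned at random to pie1-7), sites above 3 times the median depth, sites with opposite-strand variants, the denominator and a removal of the genome-wide difference, by rescaling the odds of pie1-7 so that the median difference of windows with a methylated read was 0. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, pyarrow 21.0.0 and matplotlib 3.10.9 were used.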

Results

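ARP6 is an actin-related subunit, and PIE1 the ATPase, of the SWR1 chromatin remodelling complex, which places the histone variant H2A.Z in nucleosomes. The DNA methylation of seedlings carrying arp6-5 or pie1-7 was compared, with 1 library per mutant, so that the design allows 1 comparison, pie1-7 against arp6-5. No difference here has a replicate check. The arp6-5 library listed 41854507 cytosines and the pie1-7 library 41684477, of which 41216181 were listed in both. At these shared sites the mean depth was 16.2 reads in arp6-5 and 15.1 in pie1-7. Positions are those of TAIR10.

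The mutated genes were examined first as a check of the labels. Over ARP6 the arp6-5 library listed 670 cytosines and the pie1-7 library 720, out of 728 listed in either, and the longest stretch without a listed cytosine was 30 bp in both. Over PIE1 the libraries listed 3499 and 3488 of 3570 cytosines. The longest unlisted stretch of PIE1 was 44 bp in arp6-5 and 71 bp in pie1-7, where the pie1-7 stretch held 12 cytosines read at a mean depth of 4.58 in arp6-5, close to the lower limit of the files. No stretch had the form of an insertion. Over ARP6, 58 cytosines were unlisted in arp6-5 and 8 in pie1-7, against 71 and 82 over PIE1. Genome-wide, 98.9% of the cytosines listed in pie1-7 were also listed in arp6-5. As a share of cytosines, the loss over ARP6 in arp6-5 was thus larger than over PIE1 or genome-wide, in the direction of the label. The spread of such losses over other genes was not computed, and ARP6 lies in the pericentromere of chromosome 3 as taken here. The cytosines of ARP6 that were listed had a mean depth of 13.2 reads in arp6-5 and 11.8 in pie1-7. The cause of the ARP6 loss was not tested, and PIE1 showed no such loss in pie1-7. The labels are therefore not settled by these values. The body of ARP6 had CG levels of 1.33% in arp6-5 and 1.91% in pie1-7, and that of PIE1 had 48.1% and 49.4%. Neither difference passed Fisher's exact test, with adjusted p of 0.562 and 0.525. The lower-coordinate flank of PIE1 had CHH levels of 0.823% and 0.155% (exact test, adjusted p 0.00174), a difference under the 10-point threshold; with flanks of 500 bp its adjusted p was 0.440.

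Genome-wide, CHG and CHH methylation was slightly higher in pie1-7, while the sign of the CG difference depended on how sites were weighted. Weighted by reads, CG methylation was 22.7% in arp6-5 and 22.4% in pie1-7, a difference of -0.253 percentage points with a 95% half-width of 0.0127 for counting error. As a mean over sites it was 26.2% and 26.7%, a difference of 0.482 points in the other direction, and with at least 10 reads per site the read-weighted difference was 0.0985 points. CHG methylation was 6.54% and 6.63% by reads, a difference of 0.0858 points that was 0.529 as a mean over sites. CHH methylation was 1.48% and 1.53%, a difference of 0.0518 points by reads and 0.125 over sites. CHG and CHH were higher in pie1-7 on 5 of 5 chromosomes by either weighting, whereas CG was higher on 0 of 5 by reads and on 5 of 5 by the mean over sites. On chromosome 1 the read-weighted CG difference, -0.00619 points, lay within its counting error of 0.0242 points.

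Pseudogenes, which are densely methylated, showed the widest difference in CHG among the region classes, 36.3% in arp6-5 and 37.8% in pie1-7, and their CHH levels were 6.02% and 6.51%. Pericentromeres had CHG levels of 22.4% and 23.2% and CHH levels of 3.84% and 4.10%. In protein-coding gene bodies CG methylation was 14.2% and 14.4%, CHG 0.892% and 0.941%, and CHH 0.335% and 0.350%. Chromosome arms had CG levels of 13.0% and 13.3%. Flanks within 1 kb of a gene had CG levels of 23.6% and 23.4% and CHG levels of 10.5% and 10.8%. The CHG difference of flanks was 0.308 points by reads and 0.992 as a mean over sites, and that of pericentromeres 0.828 and 1.71. The CG difference of flanks, pericentromeres and pseudogenes was negative by reads (-0.244, -0.402 and -0.316 points) and positive as a mean over sites (0.800, 0.894 and 0.663 points). Each of these read-weighted differences exceeds a counting error that treats the cytosines of one read as independent. No spread between libraries of one genotype could be set against them.

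**Figure D1:**
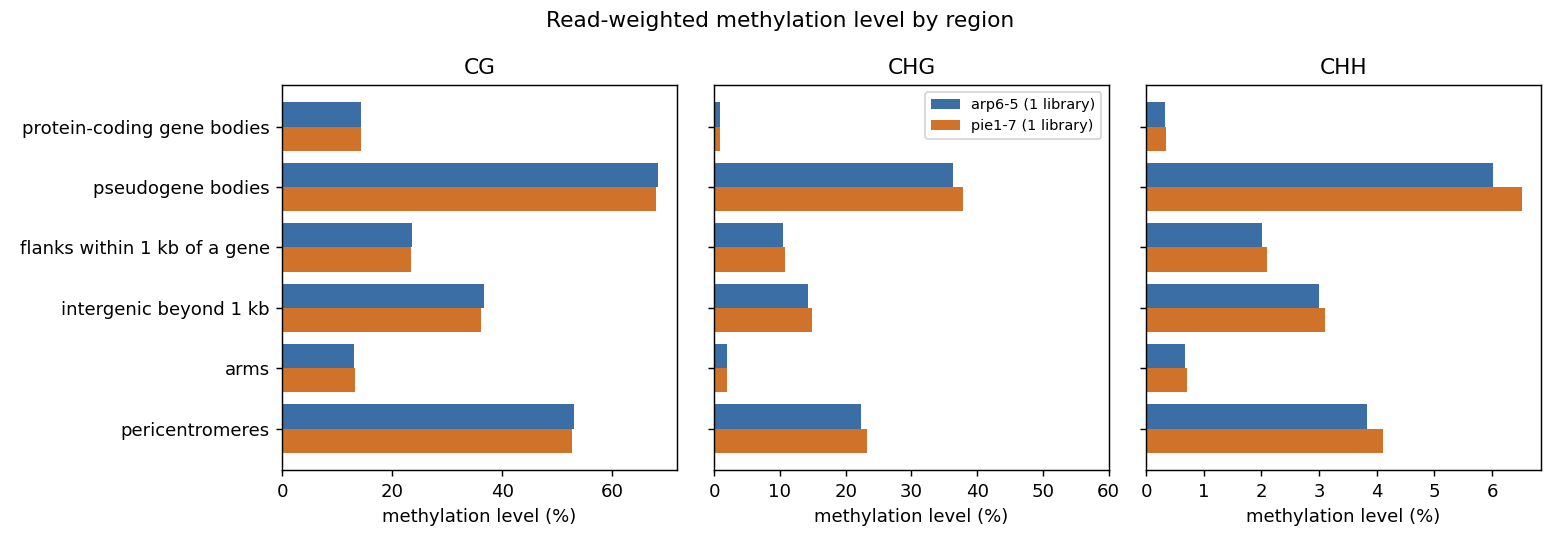
Read-weighted methylation level (%, horizontal axis of each panel) of 6 region classes in CG, CHG and CHH, with 1 bar for the arp6-5 library and 1 for the pie1-7 library; axes differ between panels. Pseudogene bodies stand at 36.3% and 37.8% in CHG, the widest gap among the classes in that context.

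**Figure D2:**
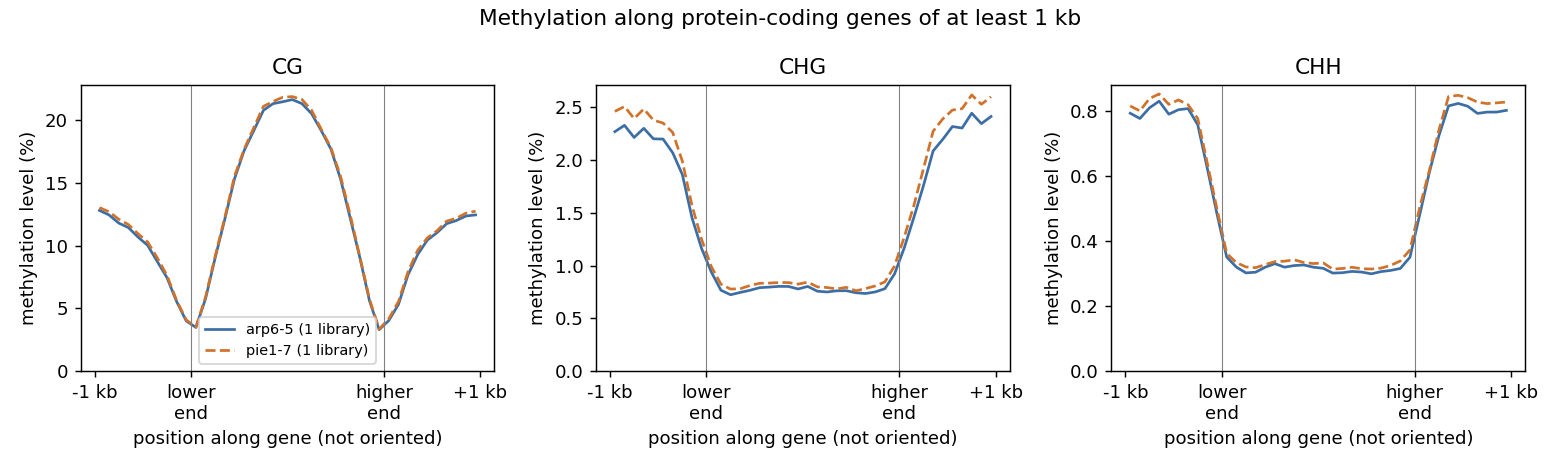
Methylation level (%, vertical axis) along protein-coding genes of at least 1 kb and their 1 kb flanks, from the lower to the higher coordinate, in CG, CHG and CHH; the solid line is the arp6-5 library and the dashed line the pie1-7 library. The lines nearly coincide, with pie1-7 slightly above arp6-5 along the whole profile in each context.

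Few 200 bp windows passed both the adjusted p and the threshold for size, and in CG and CHG most of these were higher in pie1-7. Of 500898 windows tested in CG, 601 were higher in pie1-7, going from a median of 12.04% to 66.9%, and 144 were lower, going from 58.3% to 6.62%. In CHG, 288 of 512626 windows were higher and 9 lower. In CHH, 390 of 594483 windows were higher and 343 lower. With the genome-wide difference of each context removed, the counts were 523 higher and 163 lower in CG, 176 and 21 in CHG, and 231 and 475 in CHH, where the majority turned. This removal shifts pie1-7 until the median difference of windows with a methylated read is 0; in CG that median was higher in pie1-7, opposite in sign to the read-weighted genome-wide difference. In CG the higher windows outnumbered the lower ones on each chromosome, from 62 against 13 on chromosome 4 to 154 against 41 on chromosome 1. By the adjusted p alone, without a threshold for size, 5334 windows were higher and 3056 lower in CG, 403 and 38 in CHG, and 3677 and 1778 in CHH. Counts also moved by more than 1.5 times with window length and threshold, as with 500 bp windows (103 higher and 6 lower in CG) or a CG threshold of 60 points (90 and 14).

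**Figure D3:**
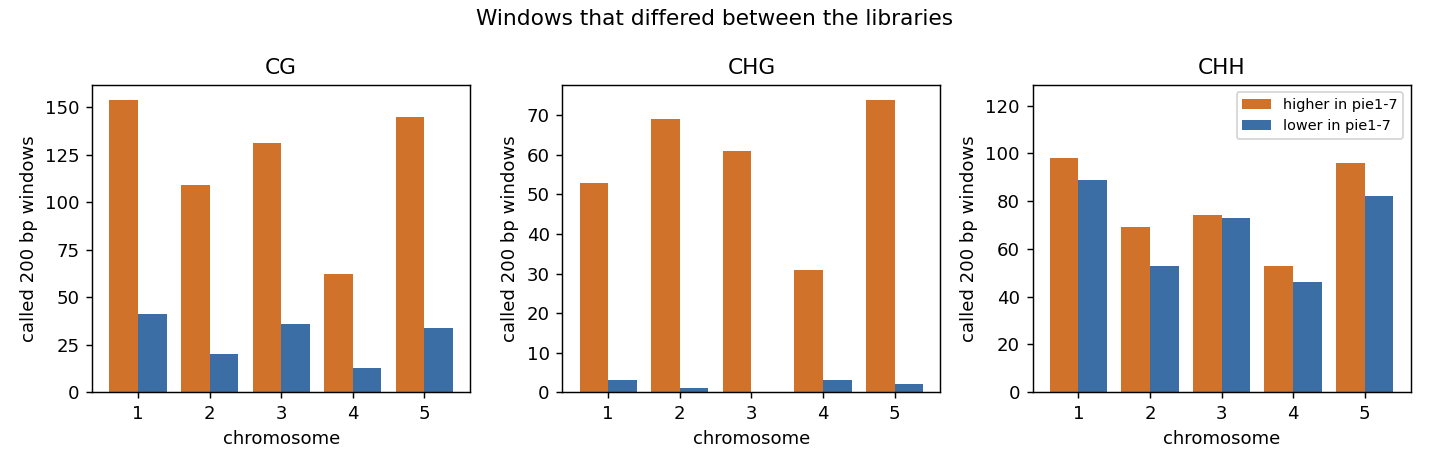
Number of called 200 bp windows (vertical axis) on chromosomes 1 to 5 in CG, CHG and CHH, with separate bars for windows higher and lower in pie1-7; axes differ between panels. In CG and CHG the higher bars exceed the lower ones on every chromosome, with 601 against 144 and 288 against 9 in all.

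The strands of one library served as the background, over 316389 CG and 341666 CHG windows with at least 4 cytosines on each strand. In CG, comparing plus with minus strand called 58 windows within arp6-5 and 88 within pie1-7, while comparing the libraries on one strand called 263 on the plus strand, 203 of them higher in pie1-7, and 294 on the minus strand, 248 of them higher. In CHG the strand comparison called 131 and 114 windows, split 63 to 68 and 60 to 54 between the strands. The libraries differed at 89 and 92 CHG windows on one strand, so CHG counts on one strand did not exceed this background. Of these windows, 85 and 89 were higher in pie1-7. The strand comparison gives no background for that direction, because an effect on a whole library would reach both of its strands.

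CG windows higher in pie1-7 lay mostly outside genes, and CG windows lower in pie1-7 lay mostly inside them. Of the 601 higher windows, 255 (42.4%) were in flanks within 1 kb of a gene, against 21.8% of the windows in which the threshold could be reached, a ratio of 1.95 (95% interval of the share of windows, 1.76 to 2.13). A further 19 lay in pseudogene bodies, a ratio of 0.130, and 178 in protein-coding gene bodies, a ratio of 0.758. Against windows of similar mean level these ratios were 3.48 in flanks, 0.525 in pseudogenes and 0.404 in protein-coding bodies. Of the 144 lower windows, 108 were in protein-coding gene bodies, a ratio of 1.92 that became 1.04 against windows of similar mean level. Arms held 403 of the higher windows, a ratio of 1.46 that turned to 0.896 against windows of similar mean level. Among the 288 CHG windows higher in pie1-7, 137 lay in flanks, a ratio of 1.60. Unlike in CG, protein-coding gene bodies held more than their share, 45 windows at a ratio of 2.11 (1.57 to 2.75), or 2.02 against windows of similar mean level. At a CHG threshold of 40 points this ratio was 1.10 (0.135 to 3.59), from 2 of 27 windows, so the excess was not seen there. Pseudogene bodies held 48, a ratio of 0.374, and intergenic sequence beyond 1 kb held 52, a ratio of 1.04. Arms held 150, a ratio of 2.44. In CHH, windows of both directions held more than their share in flanks and arms. The ratios in flanks were 1.40 for windows higher in pie1-7 and 1.52 for lower ones, and in arms 1.51 and 1.60. Within the CG windows higher in pie1-7, mean CHG methylation was 3.56% in arp6-5 and 14.4% in pie1-7, with 329 of 437 measured windows higher, and mean CHH methylation was 0.982% and 2.44%, with 469 of 601 higher. Within the CG windows lower in pie1-7, mean CHG methylation was 2.96% and 1.19%, and 47 of 121 measured windows were lower in CHG. Mean CHH methylation there was 0.969% and 0.563%, with 90 of 144 lower. In these counts a window of equal level in both libraries is neither higher nor lower, and such windows were not counted separately.

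The longest merged region spanned 6 called CG windows, at chromosome 5, 21223401 to 21224600, over the transcribed pseudogene AT5G52272. Its CG level was 26.3% in arp6-5 (768 reads) and 82.4% in pie1-7 (641 reads). Next came chromosome 2, 2939001 to 2939800, 174 bp from AT2G07080, with 14.8% and 63.5%, and chromosome 3, 10358601 to 10359200, 320 bp from AT3G27910, with 2.64% and 61.9%. All 144 CG regions lower in pie1-7 were single windows. The largest differences among these were at chromosome 1, 6286001 to 6286200, in AT1G18270 (93.8% and 14.5%), chromosome 1, 4050401 to 4050600, in AT1G12000 (86.2% and 9.09%), and chromosome 2, 2908201 to 2908400, 73 bp from AT2G07020 (80.7% and 4.0%), each over 4 cytosines. In CHH, regions higher in pie1-7 included chromosome 5, 17107201 to 17107800, 55 bp from AT5G42670, with 1.64% and 16.8%, chromosome 1, 21470201 to 21470600, 227 bp from AT1G08187, with 7.12% and 25.02%, and chromosome 1, 4110201 to 4110600, 600 bp from NRT1.1, a nitrate transporter gene, with 16.9% and 31.1%. CHH regions lower in pie1-7 included chromosome 1, 20362801 to 20363200, 177 bp from the kinase gene NEK1, with 48.0% and 26.2%, chromosome 1, 21744601 to 21745000, 710 bp from AT1G58590, with 31.5% and 15.2%, and chromosome 1, 24705001 to 24705600, 912 bp from BGLU22, with 30.3% and 15.04%.

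**Figure D4:**
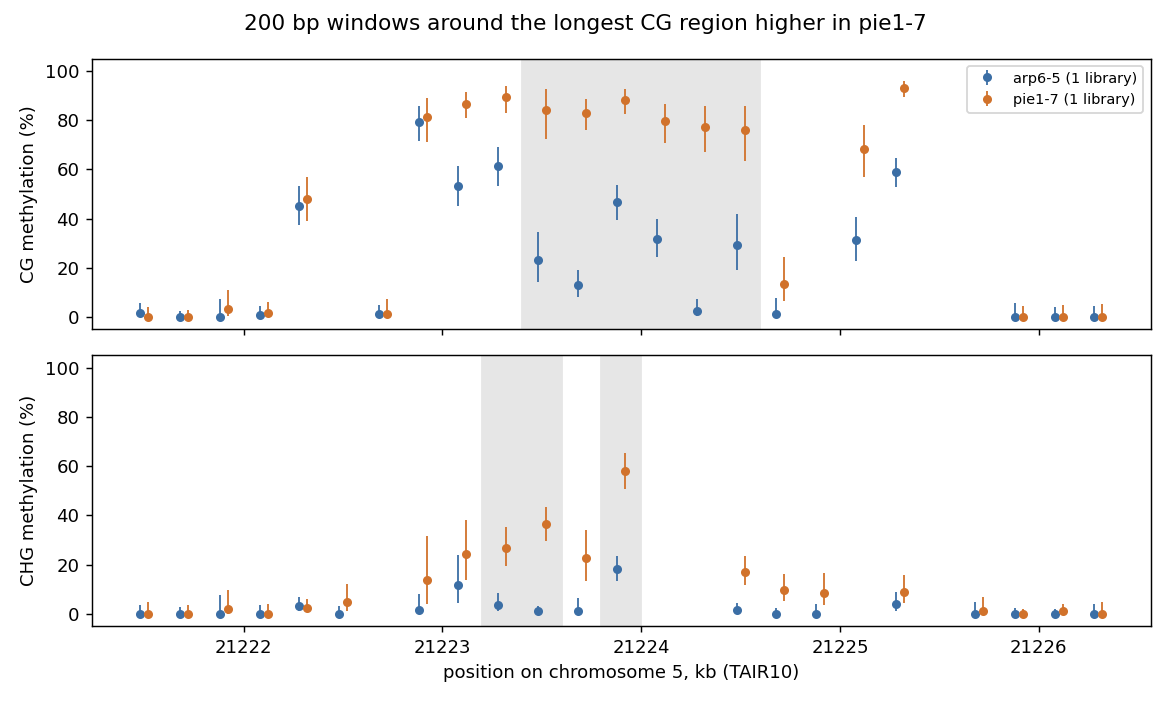
CG (top) and CHG (bottom) methylation level (%, vertical axis) of 200 bp windows along chromosome 5 (horizontal axis, kb), with 2 kb to either side of the region from 21223401 to 21224600; points are the 2 libraries, bars exact 95% intervals for counting error, and grey bands the called windows. The 6 called CG windows together stood at 26.3% in arp6-5 and 82.4% in pie1-7.

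Over whole gene bodies, CG methylation was higher in pie1-7 at 38 of 36024 genes and lower at 2. By the adjusted p alone, 1523 bodies were higher and 929 lower. Of the 38, 21 were RNA genes, 13 protein-coding genes and 4 pseudogenes, while 27432 of the 37887 annotated genes were protein-coding. The 38 were small bodies, with at most 1046 summed reads in arp6-5, against a median of 1516 over tested CG bodies. No comparison with bodies of similar size was made, so this make-up does not show that RNA genes differed more often. The largest differences were at the pseudogene AT3G26486 (chromosome 3, cytosines from 9697586 to 9697897), with 12.7% in arp6-5 and 91.8% in pie1-7 over 21 CG sites (exact test, adjusted p 1.49e-67), the transcribed pseudogene AT2G06822 (chromosome 2, 2728708 to 2729075), with 11.4% and 83.0%, and the protein-coding gene AT1G09260 (chromosome 1, 2993384 to 2993819), with 26.5% and 86.4%. The 2 lower bodies were LCR11, a gene of the cysteine-rich defensin-like family, with 23.8% and 0.585%, and the tRNA gene AT1G57280, with 92.2% and 70.5%. Body CHG was higher at 16 genes and lower at 0, with 3293 higher and 1141 lower at an unadjusted p under 0.05 in Fisher's exact test, and 468 higher and 52 lower by the adjusted p alone. Body CHH passed both thresholds as higher at 1 gene and lower at 2, whereas by the adjusted p alone 1905 bodies were higher and 837 lower. With at least 10 reads per site, bodies called higher and lower were 32 and 5 in CG, 15 and 1 in CHG, and 2 and 3 in CHH.

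In the 1 kb flanks of genes, CG methylation was higher in pie1-7 at 158 of 75378 flanks and lower at 7. By the adjusted p alone, 2407 flanks were higher and 1127 lower. These flanks are plain intervals that can run through neighbouring genes. Neighbouring flanks can also share sequence, and the 158 flanks covered 141 separate places. The higher flanks belonged to 103 protein-coding genes, 32 pseudogenes and 23 RNA genes. The widest were beside AT3G26483, with 39.0% and 90.2%, AT2G07080, with 15.3% and 64.0%, and AT5G52272, with 25.7% and 71.1%. The flank beside AT3G26483 contains the body of AT3G26486, named above, so these are not separate findings. Likewise, the flank beside AT2G07080 contains the merged CG region named near that gene. That beside AT5G52272 overlaps the longest merged CG region. The widest lower flanks were beside the RNA gene AT4G05670, with 46.1% and 17.2%, emb1138 (AT5G26742), which encodes an RNA helicase of the chloroplast, with 61.98% and 33.3%, and AT3G59650, with 48.0% and 25.1%. Flank CHG was higher at 24 flanks and lower at 0, with 5304 higher and 1314 lower at an unadjusted p under 0.05 in Fisher's exact test, and 600 and 85 by the adjusted p alone. The widest CHG differences were beside AT3G42714, with 17.2% and 49.7%, AT5G32440, with 20.7% and 52.6%, and the spliceosomal RNA gene U1.3, with 27.5% and 54.3%. No flank of 1 kb reached the CHH threshold in either direction, but 19 were called higher and 5 lower with flanks of 500 bp, and 5 and 1 with at least 10 reads per site. In CHH, 11892 were higher and 7825 lower at an unadjusted p under 0.05, and 3257 were higher and 1660 lower by the adjusted p alone. With flanks of 2 kb the CG counts were 26 and 1, the CHG counts 4 and 0, and AT3G26483, AT4G05670, emb1138, AT3G59650 and U1.3 were no longer called; with flanks of 500 bp, 217 flanks were higher and 33 lower in CG, 44 and 0 in CHG, AT3G26483 and AT5G32440 were not called, and AT4G05670, emb1138 and U1.3 had too few cytosines to test. With at least 10 reads per site, the bodies of AT3G26486, AT2G06822 and AT1G57280 could not be tested.

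Of the 9 gene lists, the loci known as targets of active DNA demethylation held the one called gene. PMEI10 (AT1G62760), a gene of the pectin methylesterase inhibitor family, had a body CG level of 49.3% in arp6-5 over 1046 reads and 72.4% in pie1-7 over 758 reads (exact test, adjusted p 8.25e-20). Adjusted over the list alone, it was also the 1 called body. Of the 16 flanks of this list tested in CG, 4 passed the adjusted p, both over all flanks and adjusted over the list alone, and all 4 were higher in pie1-7 by less than 20 points: 1 flank of DOGL4 (2.16% and 14.95%), 1 of AT1G26400 (16.2% and 28.4%) and both flanks of PMEI10 (0.293% and 7.95%, 0.907% and 4.50%). ROS1, a DNA glycosylase gene of demethylation, had a body CG level of 21.3% and 22.6% (adjusted p 0.350, exact test). The list's median flank difference was 1.29 points, at percentile 98.2 of matched random lists, with 5 of 8 genes higher and 3 lower. This was the highest of 54 such percentiles over lists, regions and contexts, and the same list had a body CG median of -0.0848 points at percentile 26.95, with 3 genes higher and 5 lower, and a body CHH percentile of 7.91, the lowest of the 54.

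None of the other lists had a called member. Of the 14 imprinted or methylation-silenced genes, 3 of 28 flanks passed the adjusted p in CG, also 3 adjusted over the list alone, all higher in pie1-7: HDG9 (69.5% and 85.6%), PHE1 (10.5% and 19.0%) and QQS (78.4% and 87.6%); the list median was 2.46 points, at percentile 96.0. Among the 24 genes of the methylation machinery, 3 of 47 flanks passed, also 3 adjusted over the list alone. These were the histone methyltransferase gene SUVH5 (56.6% and 69.9%) and DRD1 (0.564% and 3.35%), which were higher, and VIM1 (2.72% and 0%, the latter with an upper bound of 0.636%), which was lower; the percentile was 78.7. Among the 13 genes of active demethylation, 2 of 26 flanks passed, also 2 adjusted over the list alone, IDM2 (0.360% and 5.08%) and DML3 (0.184% and 2.75%), both higher, at percentile 51.5. Of the 14 genes for SWR1 subunits and H2A.Z, 1 of 28 flanks passed, also 1 adjusted over the list alone: a flank of ARP6, with 33.7% in arp6-5 and 24.8% in pie1-7 (adjusted p 0.00754, exact test), at percentile 91.5. No CG flank passed, over all flanks or adjusted over the list alone, in the flowering time genes (percentile 22.7), NLR immune receptors (11.4), heat and phosphate response genes (86.0) or photosynthesis genes (71.8). The widest flank differences there were -6.20 points at TSF, a homologue of the flowering gene FT, -11.2 at LAZ5, 3.88 at the phosphate transporter gene PHT1;4 and 10.98 at LHCB2.1. FLC, the floral repressor, had body CG levels of 0.974% and 0.385% (adjusted p 0.0492, exact test) and passed neither threshold.

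In the bodies of the listed genes, CG differences past the adjusted p were also small outside PMEI10. Among SWR1 and H2A.Z genes 1 body passed, that of the subunit gene ARP4 (19.8% and 25.4%), and 2 did adjusted over the list alone. In the methylation machinery SHH1 passed (25.6% and 31.7%), and 3 bodies did adjusted over the list alone. In active demethylation APE1L (23.3% and 29.7%) and MBD7 (0.248% and 1.21%) passed, and also 2 adjusted over the list alone. Of the demethylation targets, RLP43 (1.37% and 3.55%) passed besides PMEI10, and 3 bodies did adjusted over the list alone. Lower in pie1-7 were MEA among the imprinted genes (0.903% and 0.202%), RPP8 among the NLR genes (1.16% and 0.185%) and RCA among the photosynthesis genes (5.88% and 3.56%), while the NLR gene RPP7 was higher (55.4% and 57.8%). Adjusted over the list alone, 2, 2 and 1 bodies of these 3 lists passed. No body of the flowering time or the heat and phosphate list passed, over all genes or adjusted over the list alone.

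In CHH, each region of the SWR1 and H2A.Z list past the adjusted p was lower in pie1-7, against the genome-wide direction, and none reached the 10-point threshold. These were 3 flanks, of PIE1, SWC4 and HTA11, and 2 bodies, of SWC4 and RIN1, named after their values were seen; adjusted over the list alone, 5 flanks and 2 bodies passed. The list median was -0.0234 points in flanks (percentile 23.6) and 0.0165 points in bodies (percentile 68.0). In the other lists, the CHH flanks past the adjusted p were 1 higher and 1 lower in the methylation machinery, 1 and 1 in active demethylation, 2 and 0 in the demethylation targets, 1 and 2 in the imprinted genes, and 2 and 1 in the NLR genes. The CHH bodies were 1 higher in each of the first 4 of these lists, 2 higher in the NLR genes and 1 lower in the photosynthesis genes. In CHG no flank passed over all flanks, and the bodies that did were all higher: 1 of the demethylation targets, 2 of the imprinted genes and 2 of the NLR genes. Adjusted over the list alone, the counts changed to 1 CHH flank in the methylation machinery and 4 each in the flowering time and NLR genes. In CHG they changed to 1 body of the methylation machinery, 2 of the demethylation targets and 4 of the NLR genes, and to 1 flank each of the demethylation targets and the heat and phosphate list.

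CHH methylation over the 10 photosynthesis genes, which sets an upper limit for unconverted cytosine, was 0.388% in arp6-5 (95% interval 0.343 to 0.439) and 0.262% in pie1-7 (0.224 to 0.305). LHCB2.1 had the highest level of the 10, 1.83% and 0.945%, and was the 1 body of the list past the adjusted p in CHH. Over 14640 gene bodies with CG under 2% in both libraries it was 0.180% and 0.185%, in the other direction. On chromosome 2, between 3240 and 3510 kb, depth averaged 77.8 reads in arp6-5 and 80.7 in pie1-7, as a stretch that shares sequence with the abundant mitochondrial genome would show; its CHH level was 0.637% and 0.580%.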

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

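The opposite-strand counts of G and A entered the comparisons through the effective count, and in the alternative without variant sites, but were not compared between the libraries. The limits applied to them here were chosen after they had been looked at. Among 36500744 cytosines with at least 8 opposite-strand reads in each library, 10 were read as A on the opposite strand in arp6-5 (at most 10% G) while pie1-7 had at least 90% G. In the other direction, 44 were read as A in pie1-7 alone. Both counts are given because they exceed the 3 that a count of 0 allows; no expectation from sequencing or mapping errors was computed, so they do not show that the plants carry variants there. Of the 10 sites, 8 lay in chromosome arms, and of the 44 sites, 27 did. A further 31 cytosines were read as A in both libraries, 30 of them pericentromeric. Leaving out sites with such evidence under a looser limit left the CG window counts at 601 and 144.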

How the results depend on the processing

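Same weighting of sites in both libraries, leaving out the chromosome 2 stretch and testing one strand alone were alternatives chosen after seeing the data. No paired analysis was possible because there is 1 library per genotype. The alternative of at least 1 read could not be run, since no listed cytosine has fewer than 4. Unless said otherwise the cause of a change was not tested. Genome-wide CG (-0.253 points) turned to 0.0985 with at least 10 reads, 0.482 as a mean over sites and 0.394 with the same weight per site, and was -0.271 thinned, -0.198 without the chromosome 2 stretch and -0.177 without sites of high depth. In that order, CHG (0.0858) was 0.192, 0.529, 0.415, 0.0782, 0.104 and 0.110, and CHH (0.0518) was 0.0592 with 10 reads, 0.125 as a mean over sites, 0.103 with the same weight, 0.0546 without the stretch and 0.0550 without high depth. With 10 reads, CG was 0.215 in flanks (reversed), -0.000361 in pericentromeres, 0.346 in arms, 0.246 in protein-coding bodies and -0.113 in pseudogenes; CHG was 0.453 in flanks, 0.946 in pericentromeres and 0.127 in arms; CHH was 0.0924 in flanks, 0.255 in pericentromeres and 0.463 in pseudogenes. As a mean over sites, CG reversed to 0.800 in flanks, 0.894 in pericentromeres and 0.663 in pseudogenes, and was 0.347 in arms and 0.282 in protein-coding bodies; in the order flanks, pericentromeres, pseudogenes, arms and protein-coding bodies, CHG was 0.992, 1.71, 2.05, 0.169 and 0.0888 and CHH 0.164, 0.402, 0.555, 0.0316 and 0.0212. Flanks of 2 kb gave 0.384 in CHG. In windows, higher and lower in pie1-7, CG (601 and 144) gave 1173 and 463 at 100 bp, 103 and 6 at 500 bp, 3068 and 1297 at lower thresholds, 90 and 14 at higher ones, 213 and 62 on the plus strand and 255 and 48 on the minus strand. CHG (288 and 9) gave 161 and 1 at 500 bp, 481 and 24 at an adjusted p under 0.05, 176 and 21 with the genome-wide difference removed, 27 and 1 at higher thresholds, 20 lower at lower thresholds, 92 and 5 on the plus strand and 99 and 3 on the minus strand. CHH (390 and 343) gave 928 and 686 at 100 bp, 21 and 20 at 500 bp, 2061 and 1097 at lower thresholds, 12 and 15 at higher ones, 231 higher with the genome-wide difference removed, 713 and 582 on the plus strand and 807 and 535 on the minus strand. Counts on one strand rest on fewer reads, yet in CHH they were higher than on both strands together. No strand comparison inside a library was run for CHH. In genes, 10 reads gave 5 bodies lower in CG, 1 lower in CHG and 2 higher in CHH, and 5 flanks higher and 1 lower in CHH; flanks of 2 kb gave 26 higher and 1 lower in CG and 4 higher in CHG; flanks of 500 bp gave 33 lower in CG, 44 higher in CHG, and 19 higher and 5 lower in CHH. For location, windows of similar mean level turned the ratio of CG-higher windows in arms to 0.896 and gave 3.48 in flanks, 0.404 in protein-coding bodies and 0.525 in pseudogenes; for CG-lower windows they gave 1.09 in arms, 1.27 in flanks, 1.04 in protein-coding bodies and 0.310 in pseudogenes. Higher thresholds gave 1.64 in arms, 2.34 in flanks and 0.398 in protein-coding bodies for CG-higher windows. For CHG-higher windows they gave 2.75 in arms, 2.28 in flanks and 1.10 in protein-coding bodies. The CHH difference over photosynthesis genes (-0.126) reversed to 0.00527 over gene bodies of low CG. Matching random lists also on the number of cytosines moved the flank CG percentile of the demethylation targets from 98.2 to 98.3 and of the imprinted genes from 96.0 to 94.3, and the body CHH percentile of the imprinted genes from 96.5 to 98.0. More windows were higher than lower in CG and in CHG under each window setting run. Of the results for named genes, 58 stayed called or uncalled as before when thinned, 58 without opposite-strand variants and 54 with 10 reads. The called ones among these also kept their direction, which was not compared for the uncalled ones. With 10 reads too few cytosines were left to test the bodies of AT3G26486, AT2G06822 and AT1G57280 and 1 CHG flank of ROS1. With flanks of 2 kb 5 lost the call and with flanks of 500 bp 2 did; at 500 bp the flanks of AT4G05670, emb1138, U1.3, HDG9 and LAZ5 and 1 of ROS1 held too few cytosines. At a median of 163 and 151 reads per CHG window, a step of 30 points was recovered in 180 of 200 simulated windows, and thinning left the CHG counts at 264 and 7; how far depth limits smaller differences was not tested.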

Other observations

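The windows and genes in this paragraph were singled out after their values were seen. CG and CHG differences overlapped in part: 66 windows were higher in pie1-7 in both contexts, as were 6 gene bodies, out of 38 called in CG and 16 in CHG, and 13 flanks. Among 70 tested bodies of the LCR genes, which encode cysteine-rich defensin-like peptides, CG methylation was higher in pie1-7 at LCR26 (18.3% and 55.5%) and LCR33 (15.5% and 39.4%) and lower at LCR11. In CHH, 327 bodies of genes with symbols that begin with MIR were tested, not all of them annotated as microRNA genes. Of these, 2 were lower by at least 10 points, the microRNA genes MIR5653 (29.4% and 11.9%) and MIR5651 (41.6% and 26.6%). They were the only bodies called lower in CHH at the main setting. The 1 body called higher was the pseudogene AT5G35880 (6.58% and 19.2%). With at least 10 reads per site, 3 bodies were lower and 2 higher. For the LCR and MIR genes, no comparison with other bodies of similar size was made. Flanks with higher CG methylation in pie1-7 included those of TTN8, a cohesin subunit gene (33.3% and 77.8%), FLN1 (6.64% and 49.3%), BNQ3 (0% with an upper bound of 1.55%, and 27.5%), PHF1, a gene of phosphate transporter traffic (31.6% and 59.95%), and HEN1, a methyltransferase gene for small RNAs (41.8% and 62.6%).

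The removal of the genome-wide difference was fixed beforehand, but the bounds on its shares, and the conversion test, were chosen after the result was seen. The conversion test took the place of a comparison over photosynthesis genes (-0.126 points), which had the other sign over gene bodies of low CG (0.00527), and its bounds were set when CHH levels in the CG windows were already known. Most CG and CHG windows that differed were higher in pie1-7, and the ratio of higher to lower CG windows was 4.40 after thinning for depth. With the genome-wide difference removed, 76.2% of the CG calls were still higher (95% interval 72.9 to 79.4). In CHG the share was 89.3% (84.2 to 93.3), and calls moved from 288 and 9 to 176 and 21. The removed shift in log odds was only -0.0765 in CG and -0.105 in CHG. The majority thus remained after an even shift of the measured size was taken out. Such a shift is small beside the thresholds for a call and could hardly have balanced the calls. The shares therefore do not weigh against other effects of the library. Unconverted molecules would raise CHH about as much, but in the windows called higher the CHH difference was 2.89% of the CG difference (95% interval 2.49 to 3.30 over 601 windows) and 12.2% of the CHG difference (10.99 to 13.39 over 288), against poorer conversion in pie1-7. How many single calls are noise stays open. The strands of a library gave 0.197 to 0.335 times as many CG calls as the libraries on 1 strand. That range lies across the lower of the bounds of 0.25 and 0.5 set beforehand. In CHG the strands gave 1.24 to 1.47 times as many calls. The strands of a library hold different cytosines, so calls between them need not all be noise. Genotype cannot be told apart from library, because 0 genotypes have a second library.

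The CG difference of the whole genome was negative by reads and positive by sites. One candidate explanation is that methylated DNA was read less deeply in pie1-7: the depth ratio of pie1-7 to arp6-5 was 0.944 in CG windows under 5%, 0.960 at 5 to 20%, 0.939 at 20 to 50% and 0.904 in those of at least 50%, not a steady fall but one of 4.15% from first to last, and with the same weight per site in both libraries the difference was 0.394 points. Reads of organelle origin on chromosome 2 do not account for the sign, since without sites above 3 times the median depth it was -0.177 points. Whether the depth difference comes from the library or from the plants was not tested.

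A further hypothesis was that the CG windows higher in pie1-7 may lie at borders of methylated sequence. Of the 601 windows, 283 (47.1%) had a window with at least 20% CHG methylation in both libraries within 1 kb, against 35.6% of tested windows of similar CG level, a ratio of 1.32 (1.21 to 1.44). This lies between the bounds set beforehand, 1.2 and 1.5, and leaves the hypothesis undecided. For the 144 lower windows the ratio was 0.656.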
